A study of Mus musculus with 6 samples.

How the data were processed

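Liver RNA of mice given poloxamer P-407, a surfactant copolymer, was compared with liver RNA of saline-injected mice on 2-colour Agilent arrays. Per the labels' protocols and the series' design text, 12 female C57BL/6 mice aged 7 weeks at the start, on chow with 4.4% fat, received 0.5 g/kg P-407 into the abdomen every 3 days, and livers were taken at day 96. RNA of the 12 treated mice was combined into 3 pools, and RNA of 4 saline-injected mice into 1 control pool. Every array carried 1 treated pool in Cy5 and that control pool in Cy3, and no array had the dyes exchanged. Per the labels' protocols, each RNA was split over both array types. For the cDNA array 10 ug of RNA was labelled directly, and for the oligonucleotide array 0.5 ug was labelled after linear amplification. How the RNA of single mice was assigned to pools is not given in the sources used here.

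The deposited table holds 1 log ratio per feature and array, made by the authors, and the labels do not give its log base, its centring or its direction. The deposited values were normalized by the authors in a way that the labels do not state, and were read here as log2 ratios. The largest absolute value was 6.34 on the cDNA array and 6.30 on the oligonucleotide array. A log10 scale was set aside because the log10 of the largest 16-bit scanner value is 4.82. A natural log, with a limit of 11.1, was not excluded, and on that scale every fold change would be larger than printed. The ratio was taken as treated over control from the sample titles and the dyes in the labels. The median over the non-zero features was 0.01, 0.01 and 0.01 for the 3 oligonucleotide arrays and -0.07, -0.09 and -0.02 for the 3 cDNA arrays. With zeros included, the median of every column was 0. The background correction, the normalization within arrays and the filters of the authors are not given in the sources used here. The data used here hold no scanner intensities, so signal over background is unknown for every feature, and the number of arrays limits the precision.

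Values of exactly 0 were treated as not measured. The cDNA arrays held 5082, 5332 and 3421 such features, against 92, 87 and 157 at the neighbouring values 0.01 and -0.01, and 2654 features were at 0 on all 3 cDNA arrays. The oligonucleotide arrays held 1257, 1277 and 1258 features at 0. Of these, 1257 were at 0 on all 3 arrays, and none of those named a gene. On the oligonucleotide array, 10 genes carried 1 shared ratio on each array within 0.001, namely Ahsg, Alb, Apoc1, Apoe, COX2, Fabp1, Fgb, Lars2, Pigt and Serpina1d. This set was found after the values were seen. No other ratio was shared by more than 2 genes. These genes stayed in the tests, and none passed the threshold.

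Features were named from a table of the platform annotation. Of 22575 oligonucleotide features, 18658 named 1 gene, 30 named several and 3887 named none. Of 13482 cDNA features, 7410 named 1 gene, 438 named several and 5634 named none. Only features with 1 gene entered. The gene ID of 18445 oligonucleotide and 7332 cDNA features was found in a RefSeq gene table of assembly GRCm38.p6, used for names only, and no symbol changed. Each array was centred on the median of its non-zero features, named or not. Features of a gene with a value on all 3 arrays of a type were averaged. On the oligonucleotide array 1245 genes had more than 1 feature. In 10 of these, 1 feature lay above a log2 ratio of 0.32 and another below its negative, and none of those 10 genes is named in the text.

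Each array type was tested separately with limma 3.58.1 in R 4.3.3, fitting the mean log2 ratio of the 3 pools with lmFit and eBayes against 0, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The control pool counts as 1 control sample. The test therefore leaves out the spread between control animals, and a dye effect of a gene cannot be told apart from an effect of treatment. For genes measured on all 6 arrays, the 2 arrays of a pool were averaged and tested in the same way, since both read the same RNA. The difference between array types was fitted across the 6 arrays without a block. Pool numbers pair the arrays by design. The correlation across genes of the deviations of the 2 arrays of a pool from their array type's mean was 0.06, 0.07 and 0.07 for pools 1, 2 and 3, and was negative for every other pairing. Deviations of an array type sum to 0 over its pools, so the negative values follow in part from the positive ones and add no support. A fit with the pool as a block was an alternative. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

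For gene groups, 35 lists of 1140 entries were written, of lipid, bile acid, glucose and xenobiotic metabolism, stress and immune responses, cell machinery and markers of the cell types a liver sample could hold. Of these entries 3 could not be matched to a current symbol. The shift of a list against all other genes was tested with limma's camera at its preset correlation of 0.01, over lists with at least 5 measured members, with adjustment over lists. Camera with an estimated correlation, camera on ranks and fry, which asks whether the genes of a list move one way on balance, were alternatives. With an estimated correlation, camera takes its degrees of freedom from the 3 arrays and has little power here. A list that it did not call is therefore not shown to be unshifted. The lists, the tests and the rule for named genes were fixed before the data were examined. By that rule the text names, per array type, the 10 genes with the largest positive and the 10 with the largest negative mean among those past the threshold with 1 sign on all 3 arrays. Clone and model names are counted but not named. For the average of both array types it names 5 each way, for the difference between array types the 5 largest, and for each list up to 4 members with the smallest p on either array type. Where no gene passed, it names the 5 smallest p each way. Genes named outside that rule are said to be chosen after their values were seen.

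The fits were tested on simulated data with 200 changed genes each. On the oligonucleotide array, 68.0% of changes of 0.5 and 90.0% of changes of 1 on the log2 scale were recovered, and 1.2% of the calls were false. On the cDNA array 0% of either size was recovered. For the average of both array types, 0% of changes of 0.5 and 45.0% of changes of 1 were recovered, with 4.3% false calls. The difference between array types recovered 22.0% and 51.0%, with 24.0% false calls. With the pool as a block it recovered 0% of either size. Unchanged genes were simulated around 0, with no deviation of the control pool and no dye effect. The shares of false calls leave both out and do not describe the calls in the real data. Alternatives covered the centring, the scaling between arrays, the level, missing values, the prior, the test, a fold minimum, a stricter threshold and each pool left out. Keeping zeros as values, centring on named genes and counting list members with each pool left out were added after the data were seen.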

Results

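The series describes a mouse model of chronic hyperlipidemia, in which repeated injection of poloxamer P-407, a surfactant copolymer that raises blood lipids, is compared with saline. Liver RNA was measured at day 96 on 6 arrays. Each of 3 pools of treated livers was read on 1 oligonucleotide array and 1 cDNA array, always against the same pool of 4 control livers. The values are ratios of treated over control, read as log2, so a positive value means more RNA in the treated livers. The oligonucleotide array gave values on all 3 arrays for 16871 genes and the cDNA array for 5011, with 4702 genes on both. The files hold ratios and no intensities, and the number of arrays limits their precision.

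Which genes differed between treated and control livers was asked first on the oligonucleotide array. Markers of macrophages were among the largest increases, and genes of cholesterol synthesis, fat synthesis and the circadian clock were among the largest decreases. Gpnmb, a glycoprotein of phagocytes, was 24.7-fold higher in the treated pools (log2 ratio 4.63 ± 0.07, SD, n = 3 pools, limma adjusted p = 1.13e-06). Trem2, a lipid-binding receptor of macrophages, was 19.8-fold higher (4.31 ± 0.19, adjusted p = 1.57e-05). Dbp, a transcription factor of the circadian output, was 6.21-fold lower (-2.63 ± 0.37, adjusted p = 2.60e-04), and Mfsd2a, a transporter of lysophospholipids, was 5.64-fold lower (-2.50 ± 0.25, adjusted p = 1.45e-04).

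The other leading increases were in Lgals3, which encodes galectin-3, at 2.71 ± 0.31, Clec7a, a receptor for fungal glucans, at 2.66 ± 0.16, and Gpr137b at 2.24 ± 0.21. Egr1, an immediate-early transcription factor, reached 2.11 ± 0.36, Syngr1 2.07 ± 0.21, and Arhgap25 2.06 ± 0.07. Vcam1, an adhesion molecule for leukocytes, reached 2.06 ± 0.15 and Ms4a7 2.04 ± 0.18. The other leading decreases were in Noct, a rhythmic phosphatase, at -2.40 ± 0.14, and Cd163, the haemoglobin scavenger receptor of macrophages, at -1.77 ± 0.13. Thrsp, a regulator of lipogenesis, was 4.01-fold lower. Usp2 followed at -1.73 ± 0.01, the cytokine gene Il1b at -1.71 ± 0.24, and Sqle, squalene epoxidase, at -1.62 ± 0.58. The clock gene Per2 lay at -1.60 ± 0.27 and Fdps, which makes farnesyl diphosphate, at -1.55 ± 0.57. Each of these 20 genes had 1 sign on all 3 arrays, and the largest adjusted p among them was 0.0025.

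**Figure D1:**
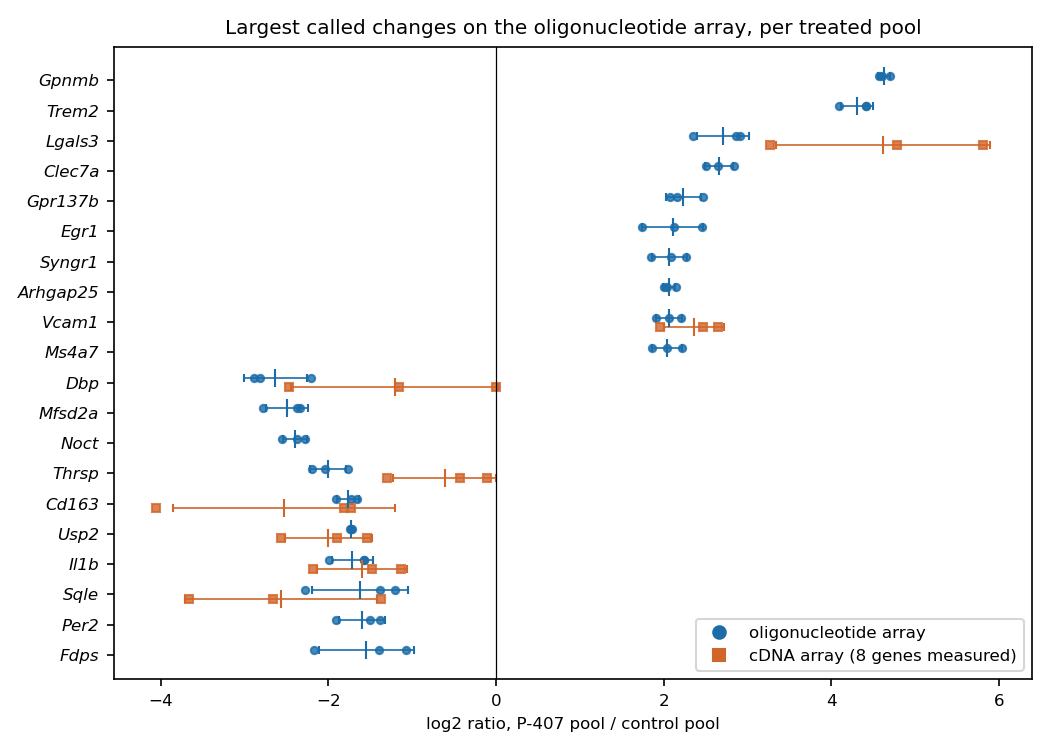
Log2 ratio of each treated pool over the control pool for the 10 largest called increases and the 10 largest called decreases on the oligonucleotide array (circles), with the same genes on the cDNA array where measured (squares, 8 genes). Vertical marks and bars give the mean and SD of 3 pools, and Gpnmb at 4.63 and Trem2 at 4.31 stand furthest to the right on the oligonucleotide array.

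In all, limma called 7318 of 16871 genes on the oligonucleotide array (43.4%), 3710 higher and 3608 lower, with 8868 genes at an unadjusted p under 0.05. Most called changes were small. At 2-fold or more, 101 genes were higher and 41 lower. Of 864 genes of chemosensory receptors (Olfr, Vmn and Taar families), which the nose rather than the liver uses, 313 were called (36.2%, exact 95% interval 33.0 to 39.5), against 43.8% of the other genes. Of these 313, 95 were higher and 218 lower, with 6 at 1.5-fold or more and 0 at 2-fold or more. Their median absolute log2 ratio was 0.25 and their largest 0.92. Many genes named below as higher or lower have ratios within that range. The counts of list members below stand beside the 3710 higher and 3608 lower among all 16871 genes. Without pool 1, 4025 genes were called, and a one-sample test without the shared prior called 40. All arrays shared 1 control pool and 1 dye orientation, so these counts leave out the spread between control animals and include any dye effect of a gene.

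Macrophage markers rose as a group. Of 41 measured members of the list of macrophage and Kupffer cell markers, 32 were higher and 6 lower, also when adjusted over the list alone, with a mean log2 ratio of 0.94 ± 0.10 (SD of 3 pool means). The camera test gave an adjusted p of 1.87e-10 at the preset correlation and an adjusted p = 0.585 with an estimated correlation. Besides Gpnmb, Trem2 and Clec7a, the list's smallest p belonged to Cd68, a lysosomal glycoprotein of macrophages (1.61 ± 0.09). The 6 lower members, listed after their values were seen, were Cd163, Marco (-1.24), Folr2 (-1.03), Itgam (-0.43), Vsig4 (-0.17) and Ccl9 (-0.15), and 4 were lower without pool 1 or without pool 2. Of 54 lysosomal genes, 30 were higher and 6 lower (30 and 7 adjusted over the list alone), with a mean of 0.29 ± 0.04 and a camera adjusted p of 2.85e-04, and an adjusted p = 0.585 with an estimated correlation. Ctss, a protease that is also in the macrophage list, rose by 2.03 ± 0.25, Cd63 by 1.65 ± 0.21, Ctsb by 1.22 ± 0.11 and Hexa by 0.99 ± 0.14. Without the 1 shared member, 29 of 53 lysosomal genes were higher and 6 lower. Without pool 2 or without pool 3, 3 lysosomal genes of the full list were lower.

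Lists of markers of neutrophils and of lymphocytes passed camera on the oligonucleotide array as well, and the lymphocyte list had a negative mean on the cDNA array (-0.21 ± 0.26, not past the threshold). Of 14 neutrophil markers, 10 were higher and 0 lower (the same counts adjusted over the list alone), with a mean of 0.51 ± 0.14 and a camera adjusted p of 3.56e-04. With an estimated correlation this list had an adjusted p = 0.585. S100a9 was 3.99-fold higher, S100a8 rose by 1.33 ± 0.29, Camp by 0.94 ± 0.17 and Mpo by 0.53 ± 0.17. Of 25 lymphocyte and NK cell markers, 15 were higher and 0 lower (16 and 0 adjusted over the list alone), with a mean of 0.24 ± 0.07, a camera adjusted p of 1.23e-04, and an adjusted p = 0.585 with an estimated correlation. Without pool 1, 6 of them were higher. Jchain, the joining chain of antibodies, rose by 0.93 ± 0.06 and the interleukin-7 receptor gene Il7r by 0.80 ± 0.20. Ms4a1 (0.38 ± 0.02) and Cd79b (0.53 ± 0.21), both of B cells, were also higher, while on the cDNA array Ms4a1 was -0.64 ± 0.47 and Cd79b -1.12 ± 1.58, neither called. Of 35 interferon-response genes, 24 were higher and 0 lower (25 and 0 adjusted over the list alone), and the 3 pool means lay close together at 0.37 ± 0.01. The camera adjusted p was 1.04e-08, and the adjusted p = 0.465 with an estimated correlation. Cxcl10 rose by 0.99 ± 0.10, Ifit1 by 0.80 ± 0.07, Gbp2 by 0.75 ± 0.08 and Gbp3 by 0.57 ± 0.02.

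Genes of connective tissue rose moderately. Of 39 genes of stellate cells and fibrosis, 27 were higher and 3 lower (30 and 4 adjusted over the list alone), with a mean of 0.29 ± 0.03, a camera adjusted p of 4.16e-06, and an adjusted p = 0.585 with an estimated correlation. Vim, the intermediate filament vimentin, rose by 1.49 ± 0.25, Mgp, an inhibitor of calcification, by 1.15 ± 0.17, and the collagen gene Col3a1 by 0.85 ± 0.05, while the matricellular gene Ccn2 fell (-0.85 ± 0.17). Of 38 cell cycle genes, 16 were higher and 5 lower (the same adjusted over the list alone), with a mean of 0.17 ± 0.07, a camera adjusted p of 0.0107, and an adjusted p = 0.688 with an estimated correlation. Its smallest p belonged to Mcm3 (0.82 ± 0.14) and Mcm6 (0.83 ± 0.16) of the replicative helicase, the cell cycle inhibitor gene Cdkn1a (0.69 ± 0.16) and Cks2 (0.42 ± 0.05). With fry, the adjusted p of the cell cycle list was 0.0907. Of 58 ribosomal protein genes, 24 were higher and 2 lower (24 and 3 adjusted over the list alone), led by Rpl38 (0.34 ± 0.10), Rps29 (0.29 ± 0.07), Rplp1 (0.28 ± 0.06) and Rps20 (0.25 ± 0.06). The mean of that list was 0.09 ± 0.02, with a camera adjusted p of 0.0075 and an adjusted p = 0.649 with an estimated correlation. Without pool 1, 8 ribosomal protein genes were higher, and without pool 2, 9. With either of these pools left out, 2 cell cycle genes and 1 ribosomal protein gene were lower, and 1 gene of stellate cells and fibrosis was lower without pool 2 or without pool 3.

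Genes of cholesterol synthesis were lower wherever they were measured. All 17 measured genes were lower, also when adjusted over the list alone and with any 1 pool left out, with a mean of -0.99 ± 0.34. Pool 2 had the lowest mean, at -1.37. The camera adjusted p was 2.20e-08 at the preset correlation of 0.01. The estimated correlation of these genes was 0.86, so they moved together and that p is likely too small. With the estimated correlation the camera adjusted p was 0.585, and with fry the adjusted p was 0.0495. Besides Sqle and Fdps, Cyp51 lay at -1.16 ± 0.17, Hsd17b7 at -0.85 ± 0.24, the lanosterol synthase gene Lss at -0.80 ± 0.20 and Tm7sf2 at -0.70 ± 0.04. Of 10 genes of sterol uptake and feedback, 3 were higher and 4 lower (3 and 5 adjusted over the list alone), and the list did not pass camera (mean -0.05 ± 0.06, camera adjusted p = 0.662). Insig2, which holds the sterol sensor in the endoplasmic reticulum, rose by 0.92 ± 0.14, the lysosomal lipase gene Lipa by 0.65 ± 0.16, and Npc2 by 0.29 ± 0.13, while Stard4 fell (-0.94 ± 0.16). Npc2 was not called without pool 1, and 2 genes of this list were lower without pool 1 or without pool 2.

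Genes of fatty acid and triglyceride synthesis fell too. Of 24 measured, 14 were lower and 3 higher (16 and 3 adjusted over the list alone), with a mean of -0.41 ± 0.12, a camera adjusted p of 7.93e-04, and an adjusted p = 0.585 with an estimated correlation. Besides Thrsp, Me1, malic enzyme, lay at -0.78 ± 0.16, Dgat2, which makes triglycerides, at -0.77 ± 0.09, and Lpin1 at -0.71 ± 0.09. Of 27 apolipoprotein and lipoprotein genes, 6 were higher and 6 lower, also adjusted over the list alone (mean -0.01 ± 0.04, camera adjusted p = 0.351). Lpl, the lipase that P-407 is known to inhibit, rose by 1.88 ± 0.11. Apoa5 (-0.91 ± 0.11), Mttp (-0.50 ± 0.03) and Vldlr (-0.48 ± 0.04) fell. Of 15 LXR targets, 4 were higher and 3 lower (4 and 5 adjusted over the list alone), with the sterol exporters Abcg1 at 1.24 ± 0.18 and Abca1 at 0.55 ± 0.12 among the higher and Mylip (-0.31 ± 0.08) among the lower (list mean 0.16 ± 0.04, camera adjusted p = 0.687, fry adjusted p = 0.0286). Of 42 genes of fatty acid oxidation and PPARA targets, 6 were higher and 6 lower (6 and 3 adjusted over the list alone), with a mean of -0.01 ± 0.11 (camera adjusted p = 0.617). Pdk4, a brake on glucose oxidation, rose by 1.29 ± 0.24 and Hsd17b4 by 0.29 ± 0.08, while Acot3 (-0.89 ± 0.14) and Ppara (-0.53 ± 0.15) fell. Of 27 bile acid genes, 3 were higher and 10 lower (4 and 13 adjusted over the list alone), with a mean of -0.14 ± 0.08 (camera adjusted p = 0.0797, and 0.0116 without pool 3). Cyp39a1 (-1.17 ± 0.13), Akr1d1 (-0.58 ± 0.09), Cyp27a1 (-0.46 ± 0.20) and Abcc2 (-0.34 ± 0.12) were the leading lower members. Leaving out pool 1 left 1 gene of fat synthesis and 3 of fatty acid oxidation higher and 6 bile acid genes lower, and leaving out pool 3 left 1 gene of fat synthesis higher.

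Genes of differentiated hepatocyte functions were lower in the same pools in which the macrophage markers averaged 0.94. Of 27 hepatocyte markers, 15 were lower and 3 higher (19 and 3 adjusted over the list alone), with a mean of -0.32 ± 0.02, a camera adjusted p of 6.59e-05, and an adjusted p = 0.585 with an estimated correlation. Tat (-1.23 ± 0.26), Tdo2 (-0.91 ± 0.13), Ass1 (-0.70 ± 0.05) and Arg1 (-0.70 ± 0.03), enzymes of amino acid breakdown and the urea cycle, had the smallest p. Alb, Ahsg and Serpina1d, abundant transcripts of hepatocytes, carried the ratio that 10 genes shared on each array (mean -0.28, with pools at -0.05, -0.21 and -0.57). Without these 3 members the mean of the other 24 was -0.33, with 15 lower and 3 higher. Of 44 phase I xenobiotic genes, 24 were lower and 4 higher (26 and 4 adjusted over the list alone), with a mean of -0.20 ± 0.05, a camera adjusted p of 5.97e-05, and an adjusted p = 0.585 with an estimated correlation. Cyp2a4 (-0.99 ± 0.15), the xenobiotic receptor gene Nr1i2 (-0.54 ± 0.14) and Ces1e (-0.46 ± 0.10) fell, while Cyp2c23 rose by 0.46 ± 0.12. Of 37 phase II conjugation genes, 21 were lower and 1 higher (25 and 1 adjusted over the list alone), with a mean of -0.28 ± 0.06, a camera adjusted p of 2.00e-06, and an adjusted p = 0.465 with an estimated correlation. Sult1a1 (-0.76 ± 0.06), Nnmt (-0.69 ± 0.19), Gstt3 (-0.55 ± 0.04) and Sult1d1 (-0.51 ± 0.13) led it. Leaving out pool 1 left 1 hepatocyte marker and 1 phase I gene higher, leaving out pool 3 left 1 phase I gene higher, and leaving out any pool left 0 phase II genes higher.

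Of 27 glucose metabolism genes, 13 were lower and 3 higher (13 and 4 adjusted over the list alone), with a mean of -0.18 ± 0.06, a camera adjusted p of 0.0032, and an adjusted p = 0.585 with an estimated correlation. Gpt2 (-0.79 ± 0.01), the glucose transporter gene Slc2a2 (-0.73 ± 0.12), Pck1 of gluconeogenesis (-0.73 ± 0.20) and the fructokinase gene Khk (-0.57 ± 0.08) fell. Without pool 1, 8 of these genes were lower. Of 28 genes of the unfolded protein response, 13 were lower and 3 higher (13 and 4 adjusted over the list alone), with a mean of -0.16 ± 0.02, a camera adjusted p of 0.0268, and an adjusted p = 0.585 with an estimated correlation. Herpud1 (-1.03 ± 0.39), the chaperone gene Hspa5 (-0.69 ± 0.08), Manf (-0.66 ± 0.09) and Creld2 (-0.53 ± 0.03) fell, and without pool 2, 8 members were lower and 1 higher.

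**Figure D2:**
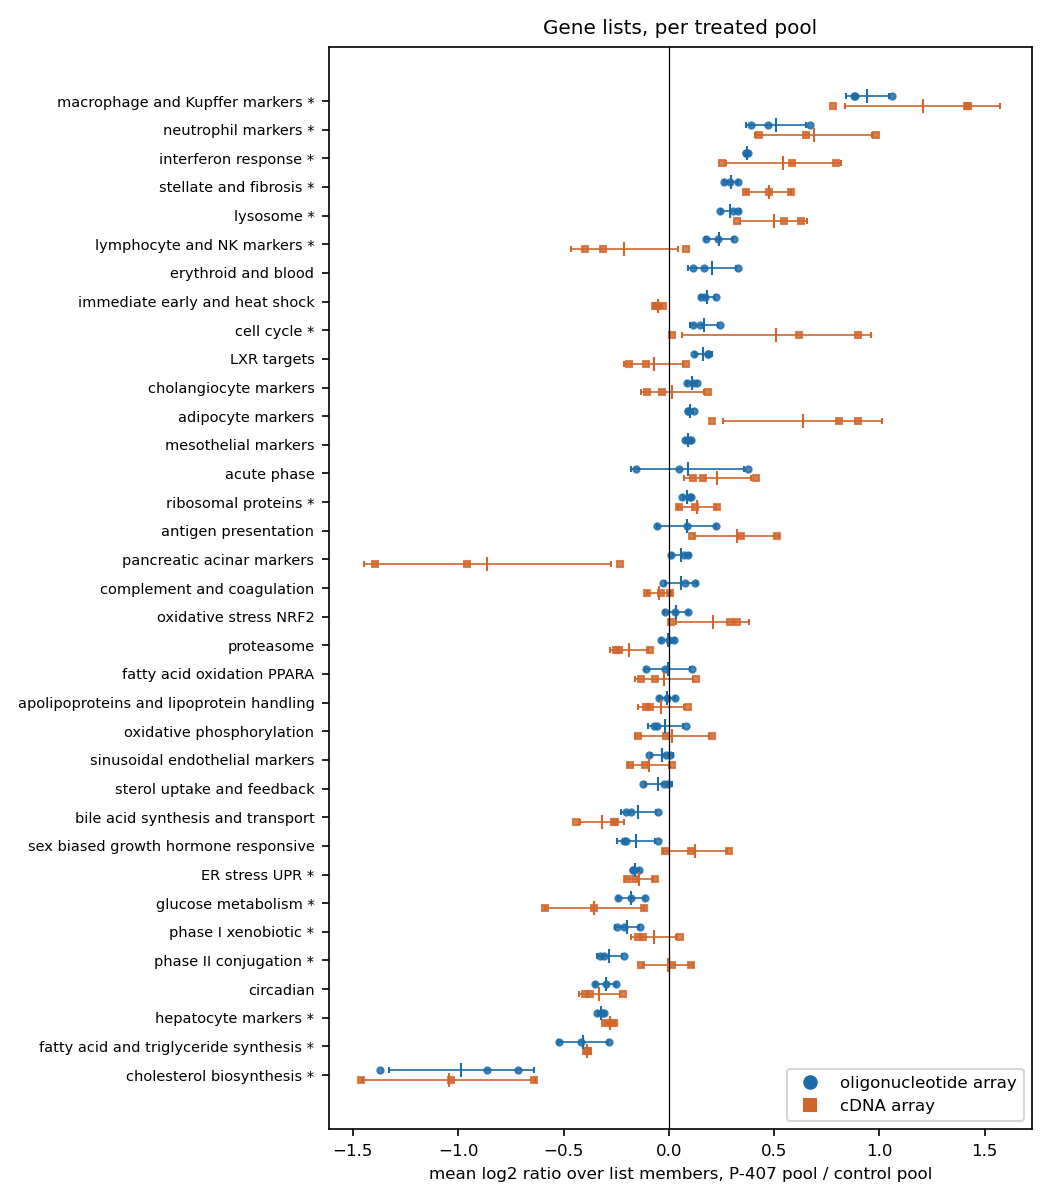
Mean log2 ratio over the measured members of each gene list, for each treated pool on the oligonucleotide array (circles) and the cDNA array (squares), with the mean and SD of 3 pools. An asterisk marks a camera adjusted p under 0.05 on the oligonucleotide array at the preset correlation; the macrophage list lies at 0.94 and cholesterol synthesis at -0.99.

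The circadian list held 5 higher and 8 lower genes among 20 (the same adjusted over the list alone). Usp2, Dbp and Per2 fell as given above, while Nfil3, a repressor of clock output genes, rose by 1.22 ± 0.11. The mean of that list was -0.30 ± 0.05, its median 0.02, and its adjusted p 0.481 with camera and 0.0260 with fry. Of 24 immediate-early and heat shock genes, 11 were higher and 5 lower (12 and 5 adjusted over the list alone), with a mean of 0.18 ± 0.04 and an adjusted p of 0.270 with camera and 0.0381 with fry. Egr1, Junb (0.84 ± 0.15) and Klf6 (0.61 ± 0.06) rose, and the heat shock gene Hspa1a fell (-0.97 ± 0.14). Of 24 sex-biased and growth hormone-responsive genes, 4 were higher and 10 lower, also adjusted over the list alone (mean -0.16 ± 0.09, camera adjusted p = 0.270). Socs2 (1.03 ± 0.27) and Hsd3b2 (0.34 ± 0.05) rose, and Cyp2b13 (-0.32 ± 0.03) fell. Of the circadian genes 3 were higher without pool 1, and of the sex-biased genes 6 were lower without pool 1 and 5 without pool 2.

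Of 30 acute phase genes, 9 were higher and 3 lower, also adjusted over the list alone (mean 0.09 ± 0.27, camera adjusted p = 0.276, and 0.0232 without pool 2). Socs3 (0.97 ± 0.35) and Hp, haptoglobin (0.55 ± 0.18), rose, while Hamp, which encodes the iron hormone hepcidin (-1.06 ± 0.29), and Slc39a14 (-0.40 ± 0.08) fell. Of 35 complement and coagulation genes, 9 were higher and 7 lower (10 and 7 adjusted over the list alone), with a mean of 0.06 ± 0.08 (camera adjusted p = 0.534). Cfp (0.54 ± 0.07) and C1ra (0.41 ± 0.04) rose, and F7 (-0.31 ± 0.04) and F12 (-0.28 ± 0.06) fell. Of 18 antigen presentation genes, 5 were higher and 2 lower (5 and 1 adjusted over the list alone), with a mean of 0.09 ± 0.14 (camera adjusted p = 0.557). H2-DMb1 (0.90 ± 0.30), B2m (0.33 ± 0.09) and Tapbp (0.29 ± 0.06) rose, and H2-D1 (-0.36 ± 0.14) fell. Of 31 genes of oxidative stress and NRF2, 10 were higher and 5 lower, also adjusted over the list alone (mean 0.03 ± 0.06, camera adjusted p = 0.534). Hmox1 (0.61 ± 0.11), Gpx3 (0.60 ± 0.04) and Txn1 (0.29) rose, and Nqo1 fell (-0.33 ± 0.13). When pool 1 was left out, 5 acute phase genes were lower, 4 complement and coagulation genes were higher and 2 lower, and 3 NRF2 genes were higher. When pool 2 was left out, 3 complement and coagulation genes were lower, 1 antigen presentation gene was lower, and 5 NRF2 genes were higher and 3 lower.

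Markers of the other cell types did not pass camera as lists, while fry called the cholangiocyte list (adjusted p = 0.0434) and the mesothelial list (adjusted p = 0.0381). Of 25 sinusoidal endothelial markers, 4 were higher and 8 lower, also adjusted over the list alone (mean -0.03 ± 0.05, camera adjusted p = 0.454). Cd34 (0.60 ± 0.04) and Aqp1 (0.28 ± 0.18) rose, the latter not called without pool 1 or without pool 2, and Gpr182 (-0.51 ± 0.14) and Flt1 (-0.37 ± 0.07) fell. Of 15 cholangiocyte markers, 6 were higher and 2 lower, also adjusted over the list alone (mean 0.11 ± 0.02, camera adjusted p = 0.270), with Ddit4l (0.51 ± 0.10), Cd24a (0.48 ± 0.18), Tff3 (0.45 ± 0.11) and Sox9 (0.27 ± 0.06) higher. Of 10 erythroid markers, 5 were higher and 1 lower, also adjusted over the list alone (mean 0.20 ± 0.11, camera adjusted p = 0.270), with Car2 at 0.69 ± 0.15, Slc4a1 at 0.47 ± 0.07, Alas2 at 0.44 ± 0.11 and Klf1 at -0.28 ± 0.01. Of 10 mesothelial markers, 4 were higher and 1 lower (5 and 2 adjusted over the list alone), with a mean of 0.09 ± 0.01 (camera adjusted p = 0.406). Gpm6a (0.38 ± 0.05), Krt18 (0.29 ± 0.16) and Efemp1 (0.27 ± 0.11) were higher and Upk1b (-0.35 ± 0.07) lower, and Krt18 and Efemp1 were not called without pool 1, nor Krt18 without pool 2. Of 15 pancreatic acinar markers, 2 were higher, Cela1 (0.51 ± 0.08) and Cela3b (0.26 ± 0.04), and 0 lower, also adjusted over the list alone (mean 0.06 ± 0.04, camera adjusted p = 0.456). Of 10 adipocyte markers, 2 were higher, Fabp4 (1.23 ± 0.21) and Pparg (0.30 ± 0.02), and 2 lower, Plin1 (-0.34 ± 0.04) and Lep (-0.23 ± 0.04), also adjusted over the list alone (camera adjusted p = 0.840). Lep was not called without pool 1. In the lists without pool 1, 1 endothelial marker was higher and 4 lower, 1 mesothelial marker was higher, 0 cholangiocyte markers were lower, 2 erythroid markers were lower and 1 adipocyte marker was lower. In the lists without pool 2, 2 endothelial markers were higher, and 1 cholangiocyte and 1 pancreatic marker were lower. In the lists without pool 3, 5 endothelial markers and 1 cholangiocyte marker were lower.

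Of 69 genes of oxidative phosphorylation, 5 were higher and 8 lower (3 and 3 adjusted over the list alone), with a mean of -0.02 ± 0.08 (camera adjusted p = 0.456, and 0.0107 without pool 2). Atp5g3 (0.37 ± 0.11) was higher, and Cyc1 (-0.39 ± 0.09) and Sdhd (-0.32 ± 0.03) were lower. Of 32 proteasome genes, 9 were higher and 8 lower (10 and 8 adjusted over the list alone), with a camera adjusted p of 0.737. Psmd14 (0.37 ± 0.03) was higher, and Psmd13 (-0.45 ± 0.09), Psmc5 (-0.37 ± 0.13) and Psmc1 (-0.26 ± 0.04) were lower. Without pool 1, 3 oxidative phosphorylation genes were higher and 2 lower, and 1 proteasome gene was higher. Without pool 2, 2 oxidative phosphorylation and 3 proteasome genes were higher, and without pool 3, 4 oxidative phosphorylation genes were lower and 5 proteasome genes higher. Mean, median and test differed in sign for 4 lists. The mean and median were 0.16 and -0.01 for LXR targets, with camera upward, -0.30 and 0.02 for circadian genes, with camera downward, 0.10 and -0.04 for adipocyte markers, with camera downward, and -0.0042 and 0.03 for proteasome genes, with camera upward.

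On the cDNA array the same pools were read with directly labelled RNA. No gene passed the threshold. Among genes with the smallest p, those with positive values were Lpl (2.27 ± 0.15), Lyz2, the lysozyme of phagocytes (2.22 ± 0.22), Arrdc3 (2.07 ± 0.23), the fatty acid-binding protein gene Fabp5 (2.57 ± 0.38) and Vcam1 (2.36 ± 0.36). Those with negative values were Cyp17a1 (-2.01 ± 0.03), Adra1b (-1.73 ± 0.08), St6galnac6 (-1.57 ± 0.12), Ier5l (-1.50 ± 0.10) and Syn2 (-2.11 ± 0.32). All 10 had an adjusted p of 0.0984 with limma. Lpl and Vcam1 were called higher on the oligonucleotide array, as was Lyz2 (1.84 ± 0.21), and Fabp5 was 0.46 ± 0.13 there. Adra1b was called in the opposite direction there (0.24 ± 0.05), Ier5l (-0.22 ± 0.09) and Syn2 (-0.21 ± 0.03) were lower there, and Cyp17a1 (-0.09 ± 0.09) and St6galnac6 (0.10 ± 0.03) were not called there.

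As lists, macrophage markers were higher and cholesterol synthesis lower on the cDNA array as well. The 26 macrophage markers had a mean of 1.20 ± 0.37 and a camera adjusted p of 1.72e-05, with 16 higher and 2 lower when adjusted over the list alone. The 35 lysosomal genes had a mean of 0.50 ± 0.16 (adjusted p = 0.0035), with 12 higher and 1 lower over the list alone. The 10 cholesterol synthesis genes had a mean of -1.05 ± 0.41 (adjusted p = 9.50e-05), with 8 lower over the list alone, and the 11 fat synthesis genes a mean of -0.387 (adjusted p = 0.0122), with 3 lower over the list alone. The 14 bile acid genes had a mean of -0.32 ± 0.10 and the 22 hepatocyte markers -0.28 ± 0.02, both with an adjusted p of 0.0362, and with 5 and 6 lower and 1 and 1 higher over the list alone. For all 6 lists the adjusted p = 0.749 with an estimated correlation, and none was called with fry. The bile acid list was not called without pool 1 or without pool 3, and the hepatocyte list not without pool 3. None of the other 26 lists measured by at least 5 genes passed camera at the preset correlation over the 3 pools. Among them the interferon list had a mean of 0.54 ± 0.27 (adjusted p = 0.0522). It was called with camera on ranks (adjusted p = 0.0478), without pool 1 (0.0393) and without pool 3 (0.0472). With an estimated correlation its camera adjusted p was 0.749, and its fry adjusted p was 0.120. Without pool 2 the glucose list was called (adjusted p = 0.0120), and without pool 3 the pancreatic acinar list (adjusted p = 0.0393), both lower. The lymphocyte list had a mean of -0.21 ± 0.26 (adjusted p = 0.235). The 20 phase II genes had a mean of -0.0038 ± 0.12 (camera adjusted p = 0.346), with 0 lower over the list alone. The 16 phase I genes had a mean of -0.07 ± 0.11 (camera adjusted p = 0.597), also with 0 lower. Except for the lymphocyte list, lists called on the oligonucleotide array had means of the same sign here. Mean, median and test did not share 1 sign for 5 cDNA lists, where camera pointed downward. Mean and median were of opposite sign for fatty acid oxidation (-0.02 and 0.02), endothelial markers (-0.10 and 0.08), cholangiocyte markers (0.02 and -0.16) and immediate-early and heat shock genes (-0.05 and 0.10), and both were positive for oxidative phosphorylation (0.02 and 0.06).

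The count on the cDNA array was 0 of 5011 genes with limma, with 1518 genes at an unadjusted p under 0.05. A one-sample test without the shared prior called 1 gene, Gspt1, whose value of 0.27 was identical on the 3 arrays at 2 decimals. The median SD of a gene over the pools was 0.32, against 0.08 on the oligonucleotide array, and the 3 cDNA arrays correlated at 0.70, 0.34 and 0.29 across genes, against 0.80, 0.79 and 0.71. In simulated data this fit recovered 0% of changes of 1 on the log2 scale, so a count of 0 does not show that genes were unchanged.

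The arrays of each pool were averaged to combine both array types. A call of the average does not mean that a gene holds on both. The largest called increases were in Lgals3 (3.66 ± 0.78), Lilr4b, an immune receptor (2.39 ± 0.40), Vcam1 (2.21 ± 0.25), Ctss (2.16 ± 0.29) and Lpl (2.08 ± 0.10). The largest called decreases were in Cd163 (-2.15 ± 0.73), Dbp (-1.92 ± 0.47), Usp2 (-1.86 ± 0.26), Il1b (-1.66 ± 0.38) and Pitx3 (-1.62 ± 0.42). Pitx3 was -0.14 ± 0.09 on the oligonucleotide array, where it was not called, and -3.10 ± 0.92 on the cDNA array. The limma adjusted p was 0.0469 for Cd163 and 0.0394 for the other 9 genes. In all, 240 of 4702 genes were called, 116 higher and 124 lower, and 206 of them were called with the same sign on the oligonucleotide array. Adra1b (-0.75), Wnt2b (-1.07) and Aqp1 (-0.62), picked after their values were seen, were called lower when averaged. On the oligonucleotide array these 3 genes were called higher. With limma, 0 genes were called without pool 1 or pool 2, with 712 and 861 at an unadjusted p under 0.05. With zeros kept as values or with the one-sample test 0 were called, while 531 were called without pool 3 and 1312 with arrays scaled to equal spread.

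The 2 array types were set against each other for the same 4702 genes. Genes with large changes on the oligonucleotide array nearly all had the same direction on the cDNA array, while genes with large ratios on the cDNA array had the same direction on the oligonucleotide array in 68.7%. Of the 72 genes called at 2-fold or more on the oligonucleotide array, 69 had the same sign on the cDNA array (95.8%, exact 95% interval 88.3 to 99.1), among them Lgals3 (4.62 ± 1.28 on the cDNA array), Vcam1, Lpl and Cd163 (-2.53 ± 1.32). The share was 88.5% (82.4 to 93.0) for called genes between 1.5-fold and 2-fold, 68.0% (63.9 to 71.8) for those from a log2 ratio of 0.32 in size up to 1.5-fold, and 61.4% (58.7 to 63.9) under 0.32, where 840 of 1369 genes had the same sign. Of 588 genes at 2-fold or more on the cDNA array with 1 sign on all 3 of its arrays, 404 had the same sign on the oligonucleotide array (68.7%, 64.8 to 72.4). Over all 4702 genes the share was 58.3%, and over the 2540 not called on the oligonucleotide array 51.5% (49.5 to 53.5). Across all genes, which are not independent replicates, the mean log2 ratios correlated at r = 0.352 (rho = 0.277), and at 0.480 over the genes called on the oligonucleotide array. Both array types read the same treated RNA and the same control pool, so part of these values may come from the shared control, and with 1 control pool that part could not be simulated.

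**Figure D3:**
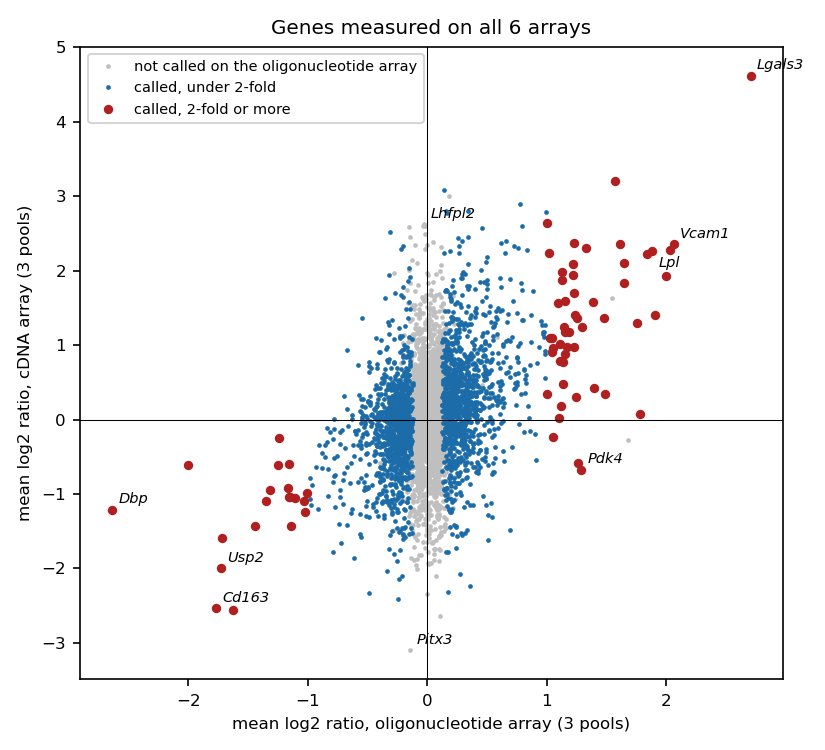
Mean log2 ratio of 3 pools on the oligonucleotide array (horizontal) against the cDNA array (vertical) for the 4702 genes measured on all 6 arrays. Of the 72 genes called at 2-fold or more on the oligonucleotide array (large points), 69 lie in the quadrants of equal sign.

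Among the list members named above as called on the oligonucleotide array, Pdk4, Mttp, Vldlr, Abca1, Nr1i2, Sult1d1, Cfp, F7, Cd79b, Ms4a1, Aqp1, Alas2, Nqo1, H2-DMb1, Rplp1, Sdhd and Psmc1 had a mean of the opposite sign on the cDNA array, and none of these passed there. The ratio itself differed between array types for 537 genes with limma, 294 with the higher ratio on the oligonucleotide array and 243 on the cDNA array. The largest differences, oligonucleotide minus cDNA, were in Pitx3 (2.96), Lhfpl2 (-2.65), Acap1 (2.58), Wnt2b (2.49) and Nell2 (2.34). On the oligonucleotide array Lhfpl2 was -0.03 ± 0.05 and Nell2 -0.0007 ± 0.03, neither called, while Acap1 (0.35 ± 0.07) and Wnt2b (0.18 ± 0.07) were called higher. With the pool as a block, since the design pairs the arrays, limma called 0 genes, with 1317 at an unadjusted p under 0.05. In simulated data the fit with a block recovered 0% of differences of 0.5 or 1, so its count of 0 does not show that the ratios were equal. Without a block, limma called 0 without pool 1 or pool 2, with 753 and 908 at an unadjusted p under 0.05, and 1062 without pool 3. In simulated data 24.0% of the calls of the fit without a block were false, a share that does not describe the real calls.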

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

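The tests of the macrophage genes and of the clock genes were chosen only after those results were seen, as was the share of equal signs among genes not called, and the other tests of the array types before.

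The treated over control ratio of 537 genes differed between the array types, a difference between groups by limma without a block. With the pool as a block 0 genes were called, by a fit that recovered 0% of differences in simulated data. Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many genes, the real one with 537, the highest other called 0, and 10 splits are too few for a share under 0.05. Calls on the oligonucleotide array with a log2 ratio under 0.32 in size shared their sign with the cDNA array in 61.4% of genes (exact interval 58.7 to 63.9), against 49.9% if their signs were independent and 51.5% among genes not called, which argues against an offset of the oligonucleotide features alone as their whole cause and leaves the shared control pool and dye orientation open. The exact interval treats genes as independent, which they are not, so it may be too narrow. An offset that needs no transcript may add to the calls, since chemosensory receptor genes were called at 82.8% of the share of the other genes. A lean of cDNA spots with little transcript towards the control dye may do so too, since 15 genes of brain, retina, lens, heart muscle and testis had a median of -0.45 there (pools -0.26, -0.80 and -0.35) against 0.0055 on the oligonucleotide array, and no biological explanation was tested.

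The largest differences, oligonucleotide minus cDNA, were 2.96 for Pitx3, -2.65 for Lhfpl2, 2.58 for Acap1, 2.49 for Wnt2b and 2.34 for Nell2, each by the test of the difference itself. By the same test, fitted without a block, 191 genes called on the oligonucleotide array differed with the opposite sign on all 3 cDNA arrays. Among these were Pdk4 with a difference of 1.96, Aqp1 with 1.81, Alas2 with 1.08, Cfp with 0.78, Mttp with -0.74 and Rplp1 with 0.58. None of these differences is established. With the pool as a block limma called 0 genes, with 1317 at an unadjusted p under 0.05. That fit recovered 0% of differences of either size in simulated data, so its count of 0 cannot decide whether they are real. Without a block, limma called 0 without pool 1 or without pool 2, with fewer arrays and with 753 and 908 genes at an unadjusted p under 0.05. In simulated data 24.0% of the calls of the fit without a block were false, a share that does not describe the real calls. Features that name no gene were outside every comparison. On the oligonucleotide array 934 of 2630 such features were called with limma (399 higher and 535 lower), and on the cDNA array 30 of 1665 (1 higher and 29 lower).

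Macrophage markers rose as a list with camera at the preset correlation (adjusted p = 1.87e-10). They were not called with an estimated correlation (adjusted p = 0.585), where camera has little power here. On the oligonucleotide array 6 of the markers were called lower (4 without pool 1 or without pool 2). These were 14.6% of the list against 21.4% of the other genes, which did not decide on a larger share of the same macrophages. At a 2-fold bound, set after that comparison, 3 of 41 were lower (Cd163, Folr2 and Marco, and 2 without pool 2). Among the 16830 other genes 38 were (Fisher's exact test, two-sided, p = 1.33e-04). That bound was set with these lower genes already seen, so the test cannot decide either. A larger share of the same macrophages therefore stays open. A lower share of hepatocytes would raise the markers of the other cell types alike, and the endothelial median lay below the macrophage median (difference -0.997, SD over the endothelial members 0.239). Other lists had positive means on this array, namely neutrophil (0.51), stellate (0.29), lymphocyte (0.24) and cholangiocyte markers (0.11). The means were 0.94 for macrophage, -0.03 for endothelial and -0.32 for hepatocyte markers. A lower share of hepatocytes as part of the cause therefore stays open. A dye effect of the amplified labelling alone is argued against by the cDNA array, where the macrophage median was 1.34 (pools 1.52, 1.38 and 0.84). A change in the state or kind of the macrophages may account for the pattern. That change, a deviation of the 1 shared control pool and the shared dye orientation stay open and were not tested.

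Several clock genes were among the largest decreases, while the whole circadian list did not pass camera (adjusted p = 0.481). Genes of the evening group, with Dbp, Per2 and Usp2 among 11 measured, had a median of -0.63 (8 lower, 1 higher), and the opposite group, with Arntl (0.78 ± 0.14) and Nfil3 among 5, had a median of 0.09 (2 higher, 0 lower, SD over members 0.55), which lies within its spread of 0. The medians lay 0.72 apart (pools 0.69, 0.68 and 0.66), mostly from the first group on this array, so livers collected at another time of day cannot be told apart from other explanations, and collection times are not given in the sources used here. A dye effect of the amplified labelling alone is argued against by the cDNA array, where the medians lay 3.05 apart (pools 3.77, 2.88 and 2.84), at -1.21 over 7 genes of the first group and 1.84 over 3 of the second, with no gene called. Per3 (0.06 and -1.75) and Clock (0.03 and 1.67 ± 1.16), picked after their values were seen, were near 0 on the oligonucleotide array only. The other members measured on both array types shared their sign. Nr1d1 of the first group was -0.01 ± 0.29 on the oligonucleotide array. A clock shifted by the treatment, a deviation of the 1 shared control pool and the shared dye orientation stay open and were not tested.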

How the results depend on the processing

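Keeping zeros as values, centring on named genes and the list members with a pool left out were tests chosen only after the data were seen. Of the named genes and lists past their threshold, 0 turned their sign under any alternative run. Of those not past it, 14 gene values and 10 lists did under at least 1, among them the acute phase mean on the oligonucleotide array (0.09, and -0.05 without pool 1). The oligonucleotide count of 7318 genes became 40 with the one-sample test without the shared prior, 565 with at least 1.5-fold, 3802 at an adjusted p under 0.01 and 4025 to 6244 with 1 pool left out, 4025 being without pool 1. The cDNA count of 0 became 1 with the one-sample test and was 0 under every other alternative run. The count of 240 for both arrays averaged became 1312 with equal spread on every array, 1309 with quantile normalization, 4602 for genes on either array type, 0 with zeros kept, 0 with the one-sample test, 0 at an adjusted p under 0.01, and 0 to 531 with 1 pool left out (0 without pool 1 or 2). Of the 240, 236 were among those called with equal spread and 205 among those without pool 3. The 537 genes that differed between array types became 0 with the pool as a block, 1077 with equal spread, and 0 to 1062 with 1 pool left out (0 without pool 1 or 2), with 483 higher and 579 lower without pool 3 in place of 294 and 243. With an estimated correlation, 0 lists were called in place of 15 and 0 in place of 6, and fry called 19 and 0, while leaving out a pool gave 15 to 17 and 6 to 7. On the oligonucleotide array the interferon and phase II lists had estimated correlations of -0.03 and 0.0002, below the preset 0.01. Their camera adjusted p was still 0.465, so a higher correlation was not why these lists were lost. The correlation of 0.352 became 0.277 by rank, 0.480 over genes called on the oligonucleotide array and 0.299 to 0.364 with 1 pool left out, and could not be given over genes called on the cDNA array, since none was. Other alternatives stayed within 1.5 times. The cause was not tested, except that leaving out a pool means fewer arrays, and stricter thresholds or folds pass fewer genes by construction. An estimated correlation leaves camera few degrees of freedom with 3 arrays.

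Of 163 named genes on the oligonucleotide array, 150 were no longer called with the one-sample test, 71 with at least 1.5-fold, 5 at an adjusted p under 0.01, 7 without pool 1, 4 without pool 2 and 1 without pool 3. Of 96 on both arrays averaged, 50 were no longer called without pool 1, without pool 2, with zeros kept, with the one-sample test or at an adjusted p under 0.01. Of 70 counts of list members, 27 moved by over 1.5 times without pool 1, 19 without pool 2 and 9 without pool 3. A filter on low values cannot be made from ratios, and leaving out features without a gene name in its place was not run, since the gene counts rest on named features alone. Signal over background, which would limit weak features, is unknown here.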

Other observations

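The test of the glucocorticoid-induced genes was planned before their values were looked up, while the genes named in the next 2 paragraphs were chosen after their values were seen.

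Further members of the lists moved on the oligonucleotide array. Among sterol genes, Idi1 (-1.50 ± 0.70) and Hmgcs1 (-1.15 ± 0.55) were lower with a wide spread between pools, as was Insig1 (-0.91 ± 0.54), a sterol-regulated gene. Among fat synthesis genes Acss2 (-1.19 ± 0.50) and Fasn, fatty acid synthase (-1.02 ± 0.43), were lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, lay at -0.20 ± 0.07. Among macrophage genes Itgax (1.34), Ccl2 (1.23) and Adgre1 (0.95) were higher. The acute phase genes Saa1, Saa2 and Saa3 had SDs of 1.46, 1.48 and 1.29 over the 3 pools and were not called. Col1a1 was higher by 0.31.

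Alb, Ahsg, Serpina1d, Apoe, Apoc1, Fabp1, Fgb, COX2, Lars2 and Pigt shared 1 ratio on each oligonucleotide array, at -0.05, -0.21 and -0.57 in pools 1, 2 and 3. Scanner intensities are not given in the sources used here, and the cause was not tested.

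Several glucocorticoid-induced genes were seen among the lower genes. Lower glucocorticoid signalling in the treated livers could be a reason, and it was tested on 14 other such genes. Their median on the oligonucleotide array was -0.19, with 6 lower, namely Klf9 (-0.58), Errfi1 (-0.95), Ddit4 (-0.75), Arrdc2 (-0.87), Sgk1 (-0.31) and Cebpd (-0.25), and 0 higher by limma, so the test did not decide. On the cDNA array, the 9 of them measured had a median of 0.32, with Sgk1 at 0.15, and none was called.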
